A study of Homo sapiens with 6 samples.

How the data were processed

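RNA was measured by sequencing in 6 libraries of T84, an established human colorectal cancer cell line. The sample titles place 3 libraries in a group with a control short hairpin RNA (shControl) and 3 in a group with a hairpin against ACSL4 (shACSL4). The series text speaks of a knockout where the titles name hairpins, so the groups are called by their titles. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed, and libraries were built after fragmentation by an NEB method. Neither the hairpin sequences nor the number of hairpins, nor a batch or a date, is given in the sources used here. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

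CASAVA, HISAT2 and the GRCh38 (hg38) build are named in the submitters' processing notes, without versions. The counting tool and its use of strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited table gives raw read counts per gene for each library, per the file headers. All 58735 gene identifiers, with their positions, names and types, were those of GENCODE release 29, and 24674 genes had no read in any library. The authors also deposited FPKM values per library, whose library size equals the median-of-ratios size factor times 1 constant. The deposited group mean signal is the mean of counts divided by those size factors, as a recomputation showed. The table further holds the authors' log2 fold changes between the groups. It also holds the authors' p-values and adjusted p-values for 30841 genes. The control columns of the table carry the prefix NC, a name the titles do not use. They were taken as shControl because NC is the only group of the table beside shACSL4, and were matched by number.

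The fold changes, tests and CPM values given here were computed from the counts. Genes were kept by filterByExpr and library sizes were scaled by TMM. Groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), without covariates. Adjusted p-values are Benjamini-Hochberg values, and a gene was called changed at an adjusted p under 0.05. Fold changes are log2 of shACSL4 over shControl. CPM uses the scaled library sizes, and levels are means ± SD over 3 libraries. At this depth a level of 3 counts corresponds to 0.171 to 0.202 CPM. Relative counting error is large near such levels and smaller above them. PCR reads without molecular identifiers are not independent molecules, so such limits cover counting error only.

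Before the data were examined, 26 gene lists were fixed for lipid metabolism, ferroptosis, stress, immune function, proliferation, intestinal cell types and markers of other cell types. All 649 list symbols were matched to the table, 3 of them through a newer symbol. Lists with at least 5 measured genes were tested with camera on log2 CPM (prior count 2, inter-gene correlation preset at 0.01). Camera with an estimated correlation and fry were run beside it. The rule for named genes was also fixed then. It took ACSL4, then the 8 largest rises and 8 largest falls among called protein coding genes with a mean of at least 50 counts and groups that do not overlap. It added up to 3 called genes with the smallest adjusted p per list, and ACSL1, ACSL3, ACSL5, CD274 and GPX4 in any case. Not every gene this rule takes is reported here. Other genes named in the text were chosen after their values were seen. Genes with near-identical copies are called uncertain, because the counting could split their reads.

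Alternatives fixed in advance were DESeq2 (1.42.0), median-of-ratios scaling, library size alone, no filter beyond 1 count, a mean of at least 50 counts, limma-voom, limma-trend on log2(FPKM + 1), the replicate number as a block, leaving out each library, protein coding genes alone, a test against a fold of 1.2, and the other list tests. Fold changes relative to the running median of 51 neighbouring genes, over all genes tested, were added after seeing the data. The running median was subtracted as a fixed value, so p-values of this setting leave out its own error. Along the chromosomes, segments were called where a running median over 51 coding genes alone passed the 95th percentile of the largest absolute value in 1000 shuffles of gene positions. Segments of 1 sign at most 25 genes apart were joined.

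The steps were tested on simulated data for this comparison, with counts drawn for the 15694 genes tested and 50 genes changed at each size. Beside these, only the genes of 1 chromosome and 1 list were shifted. The test recovered 14% of genes changed 1.25-fold, 54% at 1.5-fold, 76% at 2-fold and 94% at 4-fold. Far fewer genes changed there than in the data, where 47.2% were called, so adjustment was stricter in the simulation. These shares may therefore understate recovery in the real comparison. Of the simulated calls, 6.42% were false. Replicate pairs of a group differed by more than sampling noise, with a chi-square of 3.98 to 16.1 per degree of freedom, so no library was counted as a duplicate.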

Results

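The data were RNA-seq counts from T84 colorectal cancer cells, with 3 shControl and 3 shACSL4 libraries. ACSL4 encodes an enzyme that activates long-chain polyunsaturated fatty acids. The series title places the comparison in work on ACSL4 and immunosuppression in colorectal cancer. Total counts ranged from 14740383 to 17620630 per library. The first principal component held 70.3% of the variance and separated the groups. Mitochondrial genes took 8.99%, 9.91% and 8.13% of the counts in shControl replicates 1, 2 and 3, and 8.43%, 8.27% and 7.30% in shACSL4 replicates 1, 2 and 3.

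ACSL4 (ENSG00000068366, GRCh38 chromosome X, 109624244 to 109733403, minus strand) was lower in every shACSL4 library. Its level was 75.5, 72.2 and 72.0 CPM in shControl replicates 1, 2 and 3 and 10.3, 9.12 and 11.1 CPM in shACSL4 replicates 1, 2 and 3. The group levels were 73.2 ± 1.98 and 10.2 ± 0.979 CPM (SD, n = 3), so that 13.9% remained. The log2 fold change was -2.85 (SE 0.10), with an adjusted p of 3.6e-12 in edgeR's quasi-likelihood test. The authors' deposited table gives -2.87.

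Rises and falls were ranked among called protein coding genes with a mean of at least 50 counts and groups that do not overlap. The largest rises were in C14orf132, the interferon-induced gene IFI44L, the Wnt antagonist DKK1, RAMP1, KIF26A, RASGRF2, the insulin receptor substrate IRS1 and the amino acid transporter SLC6A20. IFI44L rose from 0.331 ± 0.182 to 7.61 ± 1.24 CPM (log2 fold change 4.47, SE 0.33), and SLC6A20 from 15.7 ± 0.446 to 166 ± 12.6 CPM (3.40, SE 0.10; SD, n = 3 for each level). C14orf132 changed by 4.51, DKK1 by 4.11, RAMP1 by 4.10, KIF26A by 3.81 and IRS1 by 3.43 on the log2 scale, and RASGRF2 went from 2.89 ± 0.462 to 32.7 ± 3.17 CPM (SD, n = 3). The largest falls were in NOD2, a sensor of bacterial peptidoglycan, complement C3, PANX2, AKR1C1, PPP1R3G, the bile acid receptor NR1H4, AKR1B10 and lipocalin LCN2. NOD2 fell from 15.6 ± 2.02 to 0.227 ± 0.0484 CPM (-6.07, SE 0.26), C3 from 25.7 ± 3.35 to 0.4 ± 0.336 CPM (-6.02, SE 0.28) and LCN2 from 194 ± 8.1 to 13.3 ± 0.61 CPM (-3.86, SE 0.10). PANX2 changed by -4.62, AKR1C1 by -4.36, PPP1R3G by -4.31, NR1H4 by -4.26 and AKR1B10 by -4.21. Some of these folds rest on few counts. NOD2, the largest fall, had 4, 3 and 4 counts in shACSL4 replicates 1, 2 and 3. In shControl replicates 1, 2 and 3, IFI44L had 9, 3 and 4 counts and RAMP1 had 10, 3 and 5. C14orf132 had 3, 11 and 3 counts in shControl replicates 1, 2 and 3, and its change was 5.39 without shControl replicate 2. In shACSL4 replicates 1, 2 and 3, C3 had 12, 2 and 5 counts and NR1H4 had 10, 0 and 6. Without shACSL4 replicate 1, C3 changed by -6.88 and NR1H4 by -5.09, and NR1H4 changed by -3.64 without shACSL4 replicate 2 and by -5.08 with limma-voom. Limma-trend on log2(FPKM + 1), whose added 1 shrinks the folds of low values, gave 0.97 for C14orf132, 0.74 for IFI44L, 2.96 for DKK1, 2.23 for RAMP1, 1.87 for KIF26A, 1.66 for RASGRF2 and 1.87 for IRS1. It gave -1.66 for NOD2, -1.95 for C3, -2.16 for PANX2, -3.74 for AKR1C1, -1.91 for PPP1R3G and -1.34 for NR1H4. Of genes named below it gave -0.97 for SLC27A1, -2.0 for ANGPTL4, 1.84 for SAMD9, 1.29 for IL33, -1.31 for PHLDA3, 1.59 for ANPEP, 2.54 for ATOH1, -1.36 for ITGA5, -1.27 for FN1, -0.19 for COL1A1, -0.64 for ITGAM and -0.51 for CD14. AKR1C1 and AKR1B10 have near-identical relatives, so their split of reads is uncertain. The running median of neighbouring coding genes was 0.50 at DKK1, 0.28 at SLC6A20 and 0.23 at AKR1C1.

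**Figure D1:**
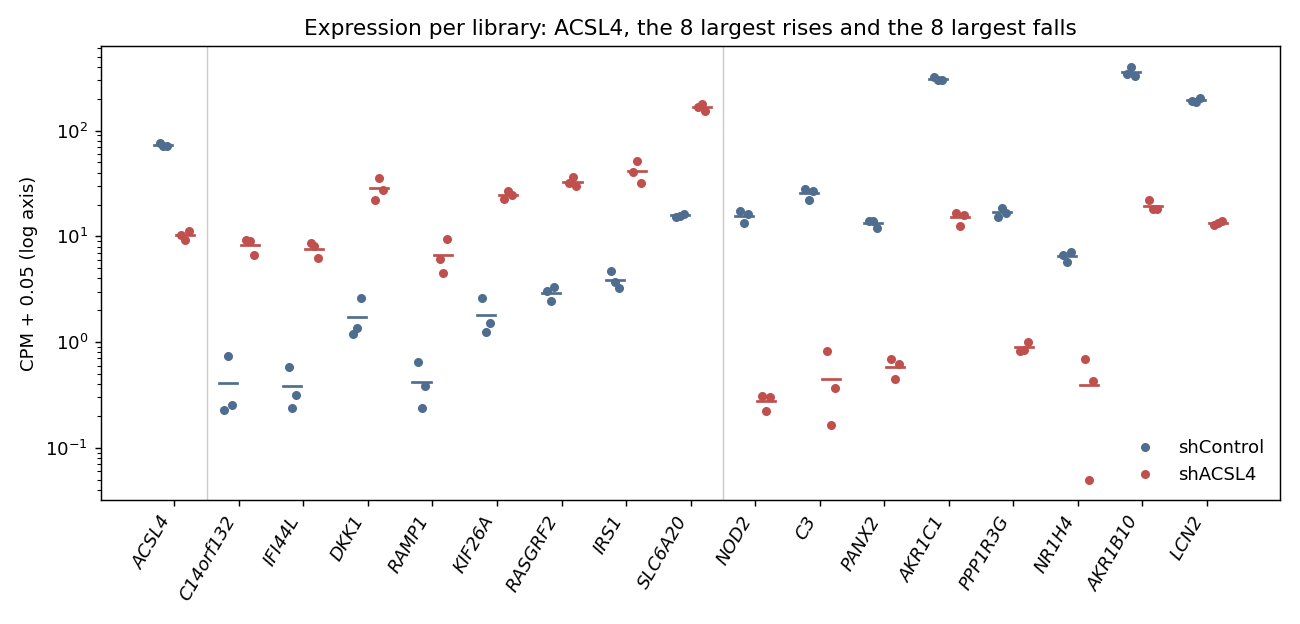
Level of ACSL4, the 8 largest rises and the 8 largest falls in each library, as CPM + 0.05 on a log axis, with points for the 3 libraries of each group and a line at their mean. Rises and falls were ranked among called protein coding genes with a mean of at least 50 counts and groups that do not overlap. The groups do not overlap for any of these genes, and ACSL4 lies at 73.2 CPM in shControl and 10.2 CPM in shACSL4.

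Of 15694 genes tested, 7400 (47.2%) changed, 3769 higher and 3631 lower in shACSL4, by edgeR's quasi-likelihood test at an adjusted p under 0.05. Beyond an absolute log2 fold change of 1 lay 1866 genes, 1076 higher and 790 lower. The groups did not overlap for 8650 genes (55.1%), where chance gives 10%. With library size alone as scaling, 65.6% of the calls were higher in shACSL4 against 50.9% here, and the median of all genes moved to 0.13. Against a fold of 1.2 there were 4650 calls, 2441 higher and 2209 lower.

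All 30 measured genes of the hypoxia and glycolysis list fell in shACSL4 (median log2 fold change -1.01; 30 lower adjusted over the list alone). Among them were the oxygen-sensing prolyl hydroxylase EGLN3 (-2.19, SE 0.10), the mitophagy receptor BNIP3 (-1.80) and the collagen prolyl hydroxylase P4HA1 (-1.71). All 24 measured genes of the NRF2 and glutathione list fell as well (median -1.01; 24 lower adjusted over the list alone). AKR1C3, an aldo-keto reductase, went from 976 ± 57.7 to 123 ± 15.6 CPM (-2.98, SE 0.11; SD, n = 3), with the same uncertainty between AKR1C copies. GCLM, which encodes a subunit of the enzyme that starts glutathione synthesis, changed by -1.84 and TXNRD1 by -1.78. Both lists had a camera adjusted p of 5.5e-14, and an adjusted p of 0.138 with an estimated correlation. With library size alone, 26 of the 30 and 23 of the 24 were called, all lower.

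Of the long-chain acyl-CoA synthetase list, 5 of 10 measured genes fell and none rose (5 lower adjusted over the list alone; camera adjusted p = 0.102, and 0.0451 without shControl replicate 3). The transporter SLC27A1 fell most (-1.64, SE 0.13), followed by ACSL1 (-0.81, SE 0.15). Over the 15 alternatives ACSL1 stayed called and ranged from -0.94 to -0.43. The running median of neighbouring coding genes at ACSL1 was -0.36, so part of its fall may be shared with them. SLC27A3 (-0.41), ACSL3 (-0.23) and ACSL5 (-0.22) were also called, with adjusted p of 0.02, 0.03 and 0.037. The ACSL3 call was lost without shControl replicate 1 or 3 (adjusted p = 0.0687 and 0.0648), without shACSL4 replicate 1, 2 or 3 (0.0934, 0.0582 and 0.0748), with library size alone (-0.11, 0.267) and with no filter (0.0568). The ACSL5 call was lost without shControl replicate 1 or 3 (0.0869 and 0.0769), without shACSL4 replicate 1 or 2 (0.0692 and 0.174), with library size alone (-0.10, 0.321), with no filter (0.0599) and relative to neighbouring genes (-0.12, 0.254). The SLC27A3 call was lost without shControl replicate 2 (0.114), without shACSL4 replicate 1 or 2 (0.0593 and 0.0559), with library size alone (0.0954), with limma-trend on FPKM (0.0621) and relative to neighbouring genes (0.0519). The calls of this list therefore fell from 5 to 3 without shControl replicate 1, with no filter and relative to neighbouring genes, and to 2 without shACSL4 replicate 1 or 2 or with library size alone.

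In the fatty acid oxidation and PPAR target list, 9 of 21 genes fell and 1 rose (9 and 1 adjusted over the list alone). The fatty acid binding protein FABP1 went from 403 ± 59.6 to 49.7 ± 2.38 CPM (-3.02, SE 0.11; SD, n = 3), the lipid droplet protein PLIN2 changed by -1.56 and ANGPTL4 by -3.61. The 1 rise became 4 with library size alone, 2 without shControl replicate 2 or shACSL4 replicate 2 and relative to neighbouring genes, and 0 without shControl replicate 3 or shACSL4 replicate 3 and with a mean of at least 50 counts. The camera adjusted p was 0.00534, and the adjusted p was 0.317 with an estimated correlation. In the fatty acid synthesis list 6 genes rose and 4 fell of 17 (7 and 4 adjusted over the list alone; 2 lower with library size alone; camera adjusted p = 0.308), with SREBF1 at 0.89, SCD at 0.92 and ELOVL1 at -0.60. The phospholipid remodelling and eicosanoid list had 7 higher (4 with DESeq2) and 6 lower of 19 (the same counts adjusted over the list alone), with TBXAS1 at -1.57 and LPCAT4 and CBR1 at -0.89. Its median was 0.12 (0.07 and 0.03 without shACSL4 replicate 1 and 3, 0.04 with no filter, 0.03 relative to neighbouring genes and 0.24 with library size alone), while its mean was -0.02 and camera pointed down (adjusted p = 0.949). The cholesterol synthesis list had 8 higher (5 without shControl replicate 3) and 3 lower (5 relative to neighbouring genes) of 23 (the same adjusted over the list alone), with MVK at 1.22 and MSMO1 at -0.91. Its median was -0.10 (-0.05 without shControl replicate 3, -0.06 and -0.03 without shACSL4 replicate 1 and 2, and 0.02 with library size alone), while its mean was 0.07 and camera pointed up (adjusted p = 0.809).

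Of the ferroptosis list, 14 genes fell and 6 rose of 28 (the same adjusted over the list alone). The transferrin receptor TFRC (-1.46, SE 0.10) and the iron transporter SLC11A2 (-0.97) fell, and the glutathione-degrading enzyme CHAC1 rose (1.39, SE 0.11). GPX4, which reduces lipid peroxides, was at 156 ± 4.43 and 151 ± 18.8 CPM (-0.05, SE 0.09, adjusted p = 0.674; SD, n = 3), in a segment of chromosome 19 where the running median of coding genes was 0.56. Relative to its neighbouring genes its change was -0.58 (adjusted p = 0.000103, against 0.189 to 0.862 in the other settings). That setting subtracts the neighbours' running median as a fixed value, so its p leaves out their spread. It does not show a fall of GPX4 itself. The list's camera adjusted p was 0.0603, and 7 of 15 alternatives called it (range over all 0.00334 to 0.0956). It was 0.0348 without shControl replicate 3, 0.0294 without shACSL4 replicate 2, 0.0485 without shACSL4 replicate 3, 0.0287 with DESeq2, 0.0177 with no filter, 0.0453 with limma-trend on FPKM and 0.00334 relative to neighbouring genes.

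In the interferon response list 30 genes rose and 6 fell of 44 (31 and 6 adjusted over the list alone; median 0.73). IFI27 went from 28.3 ± 0.503 to 109 ± 14.7 CPM (1.95, SE 0.10; SD, n = 3) and SAMD9 from 3.45 ± 0.796 to 30.9 ± 7.86 CPM (3.17, SE 0.20). UBE2L6, the conjugating enzyme for ISG15, fell (-1.86, SE 0.11), and the guanylate binding protein GBP4 changed by -3.33. IRF1 (0.04) was not called. The camera adjusted p was 3.7e-06, and the adjusted p was 0.138 with an estimated correlation. In the nucleic acid sensing list 6 rose and 2 fell of 10 (6 and 3 adjusted over the list alone; 1 fell with library size alone; camera adjusted p = 0.225), with SAMHD1 at 0.87, MAVS at 0.57 and CGAS at -0.60.

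The MHC class I presentation list moved the other way, with 15 genes lower and 1 higher of 21 (16 and 1 adjusted over the list alone; 2 higher with library size alone and relative to neighbouring genes; median -0.42). HLA-B went from 326 ± 16.2 to 127 ± 6.83 CPM (-1.36, SE 0.09; SD, n = 3), with reads that may be split between HLA copies. TAPBP, which loads peptides onto class I molecules, fell (-0.95, SE 0.08), and NLRC5, a transactivator of class I genes, rose (0.96, SE 0.09). The camera adjusted p was 0.000457, and the adjusted p was 0.138 with an estimated correlation. After trends with GC content, length and expression level were removed, the list median was -0.18. In the MHC class II list 1 of 5 genes was called, CTSS (-1.44; 1 lower adjusted over the list alone; camera adjusted p = 0.243).

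Of the checkpoint ligand and immunosuppressive molecule list, 11 genes fell and 2 rose of 19 (13 and 2 adjusted over the list alone; 1 rose without shControl replicate 2 or shACSL4 replicate 1 and with limma-trend on FPKM). TGFB1 (-1.26, SE 0.09) and CEACAM1 (-1.13, SE 0.09) fell and PVR, a ligand of TIGIT, rose (0.96, SE 0.10). CD274, which encodes PD-L1, was below the filter, with 4, 5 and 8 counts in shControl and 8, 4 and 6 counts in shACSL4, too few to show a difference at this depth. The camera adjusted p was 0.00654, and the adjusted p was 0.138 with an estimated correlation. In the chemokine and cytokine list 10 fell and 7 rose of 24 (12 and 7 adjusted over the list alone; 4 rose without shACSL4 replicate 2 or with a mean of at least 50 counts; camera adjusted p = 0.234), with CX3CL1 at -1.74, MDK at -1.21 and IL33 at 2.07. In the NF-kB feedback list 10 fell and 3 rose of 18 (the same adjusted over the list alone). Without shACSL4 replicate 1, 6 fell, and relative to neighbouring genes 1 rose. By adjusted p, not by size, LCN2, C3 and SOD2 (-0.63) came first in this list. Its camera adjusted p was 0.0225, 0.175 with genes of a mean of at least 50 counts, and the adjusted p was 0.402 with an estimated correlation.

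In the secretory and goblet list 16 genes rose and 4 fell of 23 (17 and 4 adjusted over the list alone; median 1.19, and 0.70 with limma-trend on FPKM). The mucus protein FCGBP went from 44.3 ± 8.82 to 427 ± 81.4 CPM (3.27, SE 0.15; SD, n = 3), REG4 from 10 ± 1.16 to 76.5 ± 4 CPM (2.93, SE 0.11) and ATOH1, the transcription factor of secretory lineage commitment, from 2.61 ± 0.866 to 25.9 ± 3.66 CPM (3.31, SE 0.19). The camera adjusted p was 0.000527, and the adjusted p was 0.138 with an estimated correlation. In the absorptive enterocyte list 9 rose and 4 fell of 19 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0996), with ANPEP at 2.88, CEACAM6 at 1.37 and CA2 at -1.01. In the Wnt target and stem cell list 8 fell and 3 rose of 21 (the same adjusted over the list alone; 5 rose with library size alone and 6 relative to neighbouring genes; camera adjusted p = 0.0982), with OLFM4 at -2.59, EPHB3 at 1.69 and RNF43 at -0.86.

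In the proliferation list 19 genes fell and 2 rose of 36 (20 and 3 adjusted over the list alone; median -0.32, -0.20 with library size alone and -0.19 after the same trends were removed). CDC20 (-1.23), KIF20A (-1.10) and CCNA2 (-0.72), which act in mitosis and cell cycle progression, fell. The 2 rises, MKI67 (0.47) among them, became 0 without shACSL4 replicate 1 or 2 and with limma-trend on FPKM, 1 without shControl replicate 1 or 3, with DESeq2 and relative to neighbouring genes, and 4 with library size alone. Of the others, the replication helicase genes MCM2 (0.06) and MCM6 (-0.06) were not called. The camera adjusted p was 0.000914, and the adjusted p was 0.409 with an estimated correlation. In the immediate early list 13 rose and 2 fell of 20 (14 and 2 adjusted over the list alone), with KLF6 at 1.47, JUND at 1.21 and DUSP1 at 1.22. Its camera adjusted p was 0.00534, 0.136 relative to neighbouring genes, and the adjusted p was 0.44 with an estimated correlation. In the unfolded protein and integrated stress list 12 rose and 8 fell of 28 (the same adjusted over the list alone; camera adjusted p = 0.457). PPP1R15A (1.86), TRIB3 (1.37) and SESN2 (1.27) rose, while the chaperone HSPA5 fell (-0.74). In the p53 target list 7 rose and 6 fell of 24 (7 and 7 adjusted over the list alone; camera adjusted p = 0.668), with PHLDA3 at -3.47, TP53I3 at 1.83 and POLH at -0.67.

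In the epithelial-mesenchymal list 11 fell and 4 rose (7 with library size alone) of 23 (the same adjusted over the list alone), with ITGA5 at -3.07, FN1 at -2.15 and CLDN3 at -0.90. Its camera adjusted p was 0.0568, and 5 of 15 alternatives called it (range over all 0.0169 to 0.114): 0.0348 without shControl replicate 3, 0.0169 without shACSL4 replicate 2, 0.0287 with DESeq2, 0.0397 with library size alone and 0.034 with no filter. Of 13 mitochondrially encoded mRNAs, 6 fell and none rose (6 adjusted over the list alone). The falls became 3 without shControl replicate 1, 2 without shACSL4 replicate 3 and 1 with limma-trend on FPKM, and 1 rose without shControl replicate 2 or with library size alone. The list's camera adjusted p was 0.0982, with a range of 0.0128 to 0.247, and it was called without shControl replicate 3 (0.0128), with the replicate number as a block (0.046) and with no filter (0.0281). MT-ATP8 was at -0.69 and called in all 15 alternatives. MT-CO2 was at -0.52, a call that was lost with limma-trend on FPKM (0.453). MT-ND4 was at -0.38, a call that was lost there (0.483) and without shControl replicate 1 (0.0697) or shACSL4 replicate 3 (0.0528). Markers of other cell types were few: 4 leukocyte markers were measured, of which LYZ (-2.22), ITGAM (-1.44) and CD14 (-1.10) fell (3 adjusted over the list alone). Of 3 fibroblast and endothelial markers COL1A1 was called (-1.49; 1 adjusted over the list alone, and 2 genes called with no filter), and its call was lost without shControl replicate 3 (0.0504) or shACSL4 replicate 2 (0.0534), with limma-trend on FPKM (0.0518) and relative to neighbouring genes (0.0558). These lists were too small to test.

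**Figure D2:**
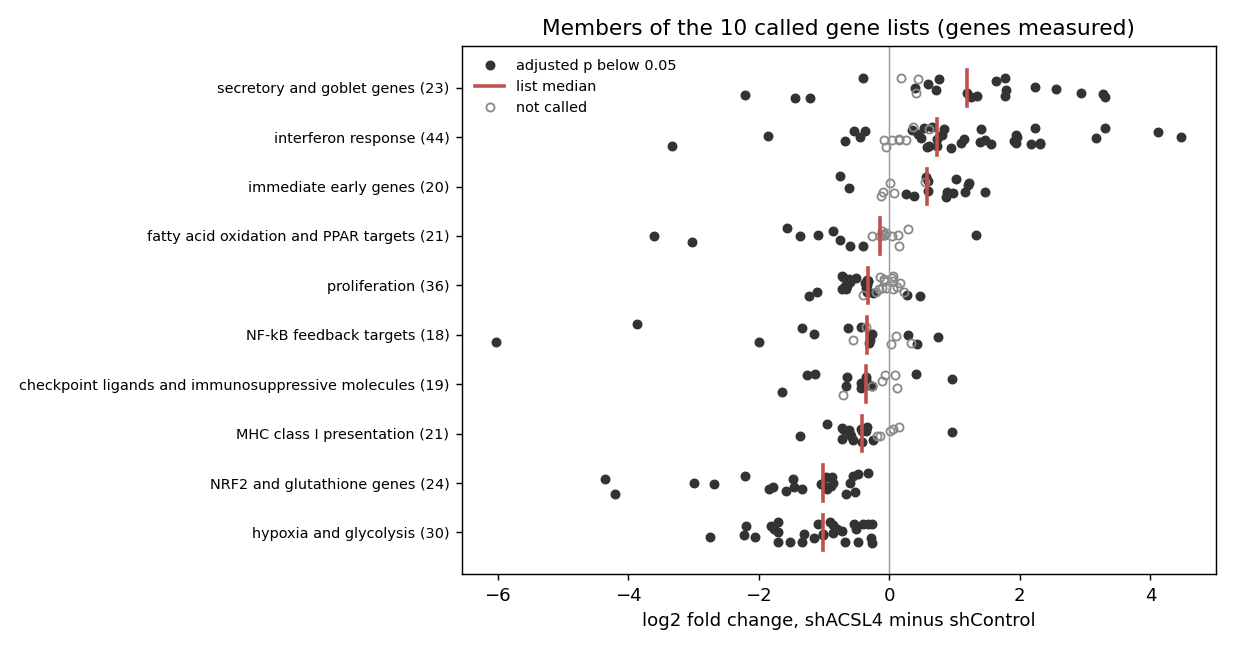
Log2 fold change (shACSL4 minus shControl, horizontal axis) of each measured gene in the 10 lists called by camera, with filled points for genes at an adjusted p below 0.05, open points for the others and a red line at the list median. All 30 hypoxia and glycolysis genes and all 24 NRF2 and glutathione genes lie below 0, also with library size alone as scaling.

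Camera with its preset correlation called 10 of the 24 lists tested, 3 higher and 7 lower. With the correlation estimated per list it called 0, with a smallest adjusted p of 0.138, and 6 lists had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 21 in 1 direction.

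Fold changes also ran in blocks along the chromosomes, a comparison chosen after seeing the data. The median coding gene was higher in shACSL4 on chromosome 10 (0.28, 484 genes), chromosome 19 (0.24, 911 genes) and chromosome 20 (0.18, 335 genes), and lower on chromosomes 17 (-0.18, 778 genes) and 18 (-0.19, 160 genes). The running median over 51 coding genes passed 0.37, the threshold from shuffled positions, in 18 segments that held 688 genes (5.47% of 12585). Of the segments, 13 held at least 20 genes, 10 higher and 3 lower. Shorter ones are less certain. On chromosome 17, stretches of 6 genes and of 1 gene were called lower by the window around them. Their own genes had medians of 0.41 and 0.46, against that direction. The start of chromosome 2, from 38814 to 24360714, had a median of 0.55 over 64 genes. The end of chromosome 8, from 140657900 to 145066685, had 0.51 over 71 genes. Chromosome 18 from 158383 to 31953136 had -0.44 over 71 genes.

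**Figure D3:**
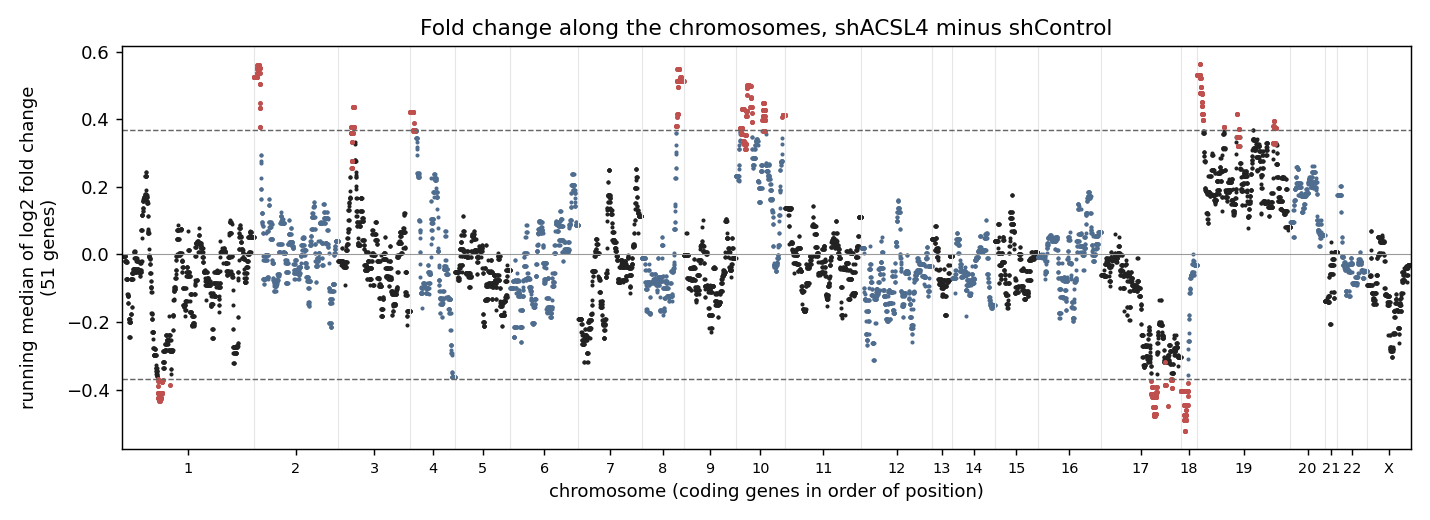
Running median of log2 fold change over 51 coding genes (vertical axis) along chromosomes 1 to 22 and X, with genes in order of position. Dashed lines mark the threshold of 0.37 from shuffled positions, and red points are genes in the 18 segments called.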

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

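The alternatives were fixed before the data were examined, apart from fold changes relative to neighbouring genes. ACSL4 stayed lower and called in all 15 alternatives run, from -2.92 to -2.27. The number of changed genes stayed within 1.5 times of 7400 except against a fold of 1.2, which by its stricter question gave 4650 calls, 2441 higher and 2209 lower. Leaving out a library gave 6122 to 7251 calls. With DESeq2, 6453 of the 7400 genes were called in the same direction, and 5989 were relative to neighbouring genes, where 5 were called in the opposite direction. Lists called numbered 0 with an estimated correlation and 21 with fry, which asks another question, against 10. The estimated correlation was -0.0188 for the secretory list and -0.033 for the checkpoint list, below the preset 0.01. Their unadjusted camera p still rose from 0.00011 to 0.0129 and from 0.00245 to 0.0302. These values argue against correlated genes as the cause for these lists. The other called lists had estimates of 0.0255 to 0.404, and the cause there was not tested. With library size alone the median of all genes was 0.13, and calls were 4878 higher and 2561 lower. The replicate number as a block gave 7414 changed genes. Deviations of same-numbered libraries correlated at 0.0623, -0.00128 and 0.00753, so the numbers gave no sign of pairing. Among single genes, GPX4, which was called only relative to neighbouring genes, changed sign with library size alone (0.069) and ranged from -0.151 to 0.027 when a library was left out, positive without shACSL4 replicate 1. Among lists that were not called, phospholipid remodelling changed direction under the block (adjusted p = 0.962) and p53 targets relative to neighbouring genes (0.971); the cause was not tested. Of the comparisons of named genes other than ACSL4, 1302 kept direction and call and 28 lost the call. Nearly all these genes were picked by their calls in these same libraries, so kept calls are not independent checks. The 1 call gained was that of GPX4 relative to neighbouring genes. Of genes changed 1.5-fold in simulation, where far fewer genes changed than in the data, 54% were recovered.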

Other observations

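Groups of genes outside the fixed lists also moved together, in families chosen by symbol after seeing the data. All 11 measured kallikrein genes, secreted serine proteases in a cluster on chromosome 19, rose (10 of them called with DESeq2), with a median log2 fold change of 1.92, among them KLK10 (1.99, SE 0.17) and KLK7 (1.62). They lie partly in a segment of 24 coding genes, from 49877425 to 51020175, with a median of 0.71, to which they contribute. The running median of coding genes was 0.37 at KLK10, about the threshold for segments. Of 14 intraflagellar transport genes, which build cilia, 10 rose and none fell (median 0.68), with IFT52 at 1.05 and IFT22 at 1.29. Of 11 UDP-glucuronosyltransferase genes 10 fell (median -1.64), but UGT1A genes share exons and their reads are uncertain. Of 47 RPL genes 28 fell and 1 rose (median -0.33), but with library size alone 14 fell (median -0.21). That scaling also moved the median of all genes, to 0.13 from 0.01, so the number of RPL calls depends on the scaling. Of 42 RPS genes, the other ribosomal protein family, 17 fell and 6 rose (median -0.15). Over 164 families, camera gave adjusted p of 0.000224 for kallikreins, 0.00421 for intraflagellar transport, 8e-05 for UDP-glucuronosyltransferases, 0.00185 for RPL and 0.478 for RPS. With an estimated correlation the adjusted p was 0.96 for each. NEUROG3 (log2 fold change 3.16, SE 0.26) and PAX4 (0.0423 ± 0.0368 to 3.31 ± 0.113 CPM; SD, n = 3), transcription factors of endocrine lineages, were higher. Among noncoding genes LUCAT1 (-3.12), the hypoxia-linked MIR210HG (-2.99) and the pseudogene NMRAL2P (-3.28) were lower.

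In the tests below, those on trends with GC content, length and expression level, on related genes, on culture and on the MHC class I list were chosen after the result was seen, and fold changes relative to neighbouring genes were added after seeing the data. With edgeR, no other split of the 6 libraries into 3 and 3 called any gene (63 to 311 genes had an unadjusted p under 0.05), against 7400 changed, 3769 higher and 3631 lower, so 1 of 10 splits gave as many. The highest other split called 9 lists, against 10. The other splits each put 2 libraries of a group with 1 of the other group. Hypoxia and NRF2 lists were called in all 9 of them, so they keep part of the difference. For some called lists a mixed split gave a smaller camera adjusted p than the real one. These were proliferation (2.13e-05 against 0.000914), immediate early (0.000227 against 0.00534) and NF-kB feedback (0.00284 against 0.0225). Their camera calls are therefore not particular to the real grouping. The remaining called lists had their smallest value in the real split, but mixed splits called several of them too. MHC class I and interferon were each called in 5 of the 9 mixed splits. The secretory list and the fatty acid oxidation list were each called in 3, the latter at 0.00692 against 0.00534. Only the checkpoint list was called in 0 of them. Among lists not called, mitochondrial mRNAs had 2.6e-07 against 0.0982. With 10 splits the share cannot fall under 0.05. Mixing the 2 groups also puts their difference into the spread within each set of 3, which holds calls of genes down. The absence of called genes in the other splits therefore does not measure chance.

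The chromosome segments shifted by a median of 0.47 in their own direction, a size raised by picking them on these same coding fold changes. Trends with GC content, length and expression level held 3.77% of the variance of coding fold changes. After removing them 0.45 was left (95% bootstrap interval 0.41 to 0.48). Intervals here treat neighbouring genes as independent, so they may be too narrow. Without zinc finger genes and related neighbours 0.44 was left. The tables thus argue against these trends and against related genes as the whole cause. Noncoding genes that overlap no coding gene, which did not define the segments, shifted the same way by a median of 0.27 over 53 genes (0.13 to 0.48), as a prediction written before it was seen required of a copy number difference between the cell populations. A candidate explanation is therefore that the populations differ in copy number, but a regional change in chromatin would shift neighbours too, and DNA was not analysed here. Genes named from such segments, or from regions short of the threshold, may carry part of their change from a regional shift. The running median of coding genes was 0.43 at TP53I3 inside a segment, and -0.285 at CDC20 and -0.26 at RNF43 outside. Other named genes, such as BNIP3 (0.41) and TGFB1 (0.34), moved against their neighbours.

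Hypoxia and glycolysis genes kept a median of -0.99 after the trends were removed and -0.97 relative to neighbouring genes, and NRF2 and glutathione genes -0.87 and -1.10, so the tables argue against these trends and chromosome segments as the whole cause. The mean hypoxia list score was 7.19, 7.22 and 7.07 log2 CPM in shControl replicates 1, 2 and 3 and 6.06, 6.04 and 5.98 in shACSL4, a difference of -17.4 within-group SDs. A difference in cell density or oxygen between the groups at harvest cannot be told apart from an effect of the ACSL4 hairpin, since every library of a group would share it. The effect of the hairpin itself, and of sequences other than ACSL4 it may reach, is also untested.

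Of 21 MHC class I genes 15 fell and 1 rose, while of 44 interferon genes 30 rose and 6 fell. Neither list was called by camera with an estimated correlation (adjusted p = 0.138 for each). Other coding genes of chromosome 6 between 29722775 and 33314387 had a median of -0.044 over 87 genes (-0.12 to 0.15), which argues against a regional shift. Without HLA genes the list median was -0.43 (-0.62 to -0.19). Reads shared between HLA copies would leave it above -0.1, so the tables argue against them as the cause of the list's fall, although the interval does not lie wholly below the bound of -0.2 set against them. Removing trends with GC content, length and expression level left 42.9% of the list median, so such a trend may account for part of the fall.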
